A study of Mus musculus with 24 samples.

How the data were processed

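RNA from fibro/adipogenic progenitors (FAPs), the mesenchymal stromal cells of skeletal muscle, was profiled on 24 Illumina 1-colour bead arrays. Per the labels, the cells were freshly sorted from pooled tibialis anterior, gastrocnemius and quadriceps muscles of wild-type male C57BL/6J mice, either uninjured or 3 days after injection of 50 µl of 50% glycerol. Mice were 2 to 4 months or 20 to 24 months old, and each of the 4 groups holds 6 arrays, which the labels call biological replicates. Per the labels' protocols, RNA was extracted with a micro column kit, checked on a Fragment Analyzer, amplified and labelled with biotin. The surface markers and gates of the sort are not given in the sources used here. A letter in the column names is constant within each group and its meaning is not given, so whatever it marks cannot be told apart from the group. No chip or scan batch is given in the sources used here.

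Per the file headers, the authors deposited a non-normalized intensity for each of 25697 probes on each array, with a detection p-value beside it. These intensities were neither background-subtracted nor normalized: the lowest signal of an array lay between 80.2 and 96.2 and the median between 95.4 and 115. The deposited detection p-value ranks a probe among the array's negative controls, in steps of 1 in 798. The authors also deposited normalized log2 values, which were used as an alternative. Every column of these log2 values had a median of 6.71, and they differed by at most 0.118 from log2 quantile-normalized intensities without background correction, so their scale and direction are known and no centring per gene was made. The submitters' processing notes name Partek, with no version or role. Signal depth on arrays has no counts, and the number of arrays limits the precision; between 6587 and 9943 probes per array had a detection p under 0.01.

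From the intensities, background was corrected with limma's nec from the detection p-values, an offset of 16 was added, and arrays were quantile-normalized and put on a log2 scale (R 4.3.3, limma 3.58.1). Probes with a detection p under 0.01 on at least 6 of 24 arrays were kept (10048 probes). Of all probes, 23978 had 1 gene symbol, 0 had several and 1719 were unnamed here; 23962 matched the RefSeq gene table by Entrez identifier. The brightest kept probe stood for a gene, and 1529 genes had over 1 kept probe. This gave 7576 named genes and 572 unnamed probes, 8148 features in all, and counts in the text are of named genes. A group in which no array detected any probe of a gene has only a bound, and the fold is then given as "at least": the bright group's mean against the dim group's mean of, per array, the higher of the lowest detected signal and the probe's own.

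Differences were tested with limma (lmFit and eBayes) in 1 model of 4 group means over 24 arrays, with 5 contrasts: activated minus quiescent in young and in old, old minus young in quiescent and in activated, and the difference between the activation changes. P-values were adjusted by Benjamini-Hochberg over all features, and a gene was called at an adjusted p under 0.05. The numbers of arrays given beside a gene count arrays of the first group lying on the stated side of the other group's mean. Errors of log2 changes are moderated standard errors (SE) from this fit, with n = 6 arrays per group. For 1 gene, Ccn4, exact 2-sided permutation tests over the 924 assignments of 12 arrays were added. It was chosen beforehand as the matricellular gene that the study of these arrays is known for. Before the data were examined, 35 gene lists, the rule for named genes and all but the added alternatives were fixed. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over lists within a contrast. A list score is the mean log2 value of its members per array. Changed members are also counted with p-values adjusted over the list alone.

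The genes named in the text are the 10 risen and 10 fallen genes with the largest mean change among those called the same way in both ages, the 10 highest and 10 lowest called genes of each age comparison, and the 8 highest and 8 lowest called genes of the interaction. Added to these are up to 4 called members of each described list, with up to 2 called the opposite way, and 16 genes named beforehand. Of these 16, Ly6a and Mki67 were not named on the array, and Col1a1, Tgfb1, Ptprc and Pax7 did not pass the detection filter. Unnamed probes and clone or predicted-model names were not eligible.

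The steps were tested on simulated data, in 5 runs with 200 changed genes among 8148 features. All groups were given the young quiescent means and the same spread per gene, averaged over the groups, with independent errors. Of 2-fold changes, 50.8% were recovered for activation in young, 44.6% for activation in old, 46.2% for age in quiescent, 44.6% for age in activated and 19.8% for the interaction. Of 4-fold changes, the recovered shares were 92.2%, 90.6%, 94.0%, 88.4% and 71.8%. The pairwise contrasts were simulated alike, so their shares differ only by the random draw. Unequal spread between groups and correlation between genes were not simulated, so the shares can be too high for the more variable old quiescent arrays. Alternatives covered background correction, scaling, the authors' values, the offset, the filter, the probe rule, the arrays in the fit, the replicate number, array weights, a variance trend, the list test and each array left out. Alternatives added after seeing the data were the omission of the pair of arrays with the lowest weights and a fit with the macrophage, lymphocyte and endothelium scores as covariates. Figures were drawn with matplotlib 3.10.9.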

Results

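FAPs sorted from uninjured muscle (quiescent) and from muscle 3 days after glycerol injury (activated) were compared in young and old mice, to ask how activation changes these cells and how age alters either state. Glycerol injection is an injury that leads to fat deposition in regenerating muscle. Each group held 6 arrays. The mean number of detected probes was 8649 ± 747.5 (SD, n = 6) in young quiescent, 8744 ± 552.7 in young activated, 8061 ± 792.9 in old quiescent and 8351 ± 1091 in old activated arrays. The first principal component held 38.7% of the variance and placed all activated arrays above all quiescent ones. Old quiescent array 2 lay nearest to the activated arrays, at -6.92 on this component. The median correlation between arrays of a group was 0.908 in old quiescent, against 0.951 in young quiescent, 0.952 in young activated and 0.940 in old activated arrays. Old activated array 4 had the fewest detected probes, 6587, and the lowest array weight, 0.294.

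**Figure D1:**
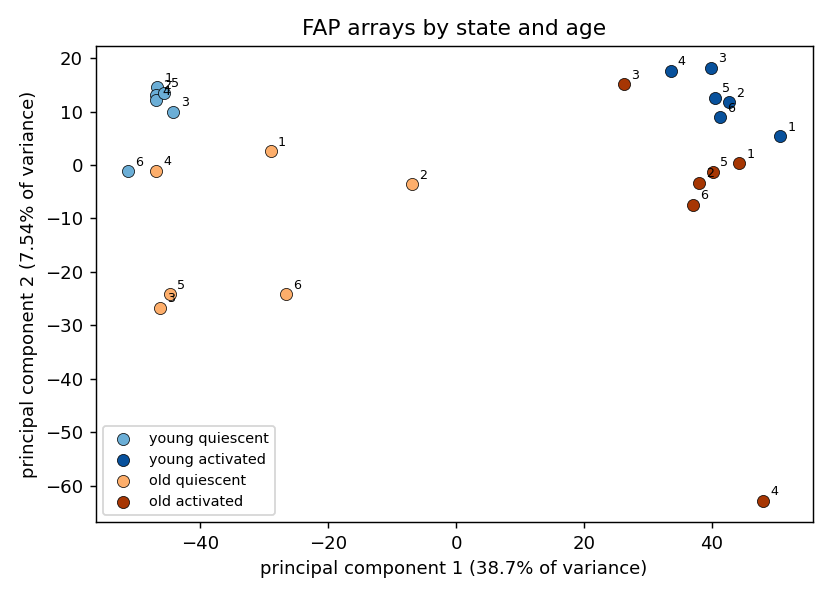
Principal component 1 (38.7% of variance) against component 2 (7.54% of variance) for 24 FAP arrays, each point an array with its replicate number, coloured by group. Activated and quiescent arrays separate along component 1, with old quiescent array 2 at -6.92, and old activated array 4 lies apart at -62.8 on component 2.

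In young mice, arrays of activated FAPs had higher cell cycle genes and lower genes of stromal identity and basement membrane. Cdca3, a cell cycle gene, rose by 5.78 ± 0.53 on the log2 scale (SE, n = 6 per group; adjusted p = 1.2e-08, higher in 6 of 6 activated arrays). Plk1, a mitotic kinase, rose 29.7-fold, the kinesin Kif2c 25.8-fold, Cdc20 22.0-fold and the centromeric histone Cenpa 18.7-fold. The replication-dependent histone genes H2ac15, H2ac11 and H2ac7 rose 31.1-, 30.2- and 29.4-fold. All 15 measured mitosis genes rose (15 adjusted over the list alone; median log2 change 2.76, camera adjusted p = 5.33e-17). Of 23 DNA replication genes 20 rose and 0 fell (22 and 0 adjusted over the list alone; median 2.23, camera adjusted p = 3.28e-15), with Tk1 up 26.2-fold, Uhrf1 12.3-fold, Mcm10 9.68-fold and Mcm5 8.75-fold. Every young activated array scored above every young quiescent array on both lists. Kif2c, Cdc20 and Mcm10 were detected on 1 and Tk1 on 2 of 6 young quiescent arrays, so their folds rest on a level near background.

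Of 20 genes that mark FAPs and fibroblasts 15 were lower in activated arrays and 0 higher (15 and 0 adjusted over the list alone; median -1.10, camera adjusted p = 4.69e-09). The macrophage score rose in the same arrays, from 7.78 ± 0.28 (SD, n = 6) to 10.7 ± 0.69. Whether FAPs made up less of the RNA was not tested. Pi16, a marker of a stromal progenitor population, changed by -3.94 ± 0.22, Vit by -3.91 ± 0.29, Dpp4 by -2.40 ± 0.33 and the proteoglycan Lum by -2.38 ± 0.31 on the log2 scale, each lower in 6 of 6 activated arrays (adjusted p = 6.75e-12 for Pi16). Pdgfra, the receptor used widely to identify FAPs, was 2.05-fold lower (adjusted p = 0.000641, 6 of 6 arrays). Ranked by the mean change over the 2 ages among genes that fell in both, the 10 lowest included Inmt (107-fold lower) and Ces1d (43.6-fold), Retnla (20.0-fold), Camk2n1 (13.3-fold), Wfdc1 (12.7-fold), Cldn10 (12.5-fold) and P2ry1 (11.1-fold). Retnla was detected on 2 of 6 activated arrays, near background. Inmt is a methyltransferase and Ces1d a carboxylesterase. Acta2, smooth muscle actin, was 1.89-fold lower (adjusted p = 0.00383, 6 of 6 arrays).

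Of 15 basement membrane and collagen VI genes 13 fell and 0 rose (14 and 0 adjusted over the list alone; median -1.39, camera adjusted p = 2.78e-09), among them Nid1 (5.96-fold), Col15a1 (4.79-fold), Hspg2 (4.08-fold) and Lamb2 (3.93-fold). In the list of TGF-beta and BMP signalling 10 of 20 fell and 0 rose (10 and 0 adjusted over the list alone; median -0.92, camera adjusted p = 1.6e-05). They included Ltbp4, a binding protein of latent TGF-beta (29.8-fold), Gdf10 (9.45-fold), the ligand Bmp4 (8.64-fold) and Ltbp1 (4.53-fold). Matrix proteases and their inhibitors went both ways, with 3 risen and 9 fallen of 17 (4 and 9 adjusted over the list alone; median -1.06, camera adjusted p = 0.0122, adjusted p = 0.125 with an estimated correlation). Timp3 (17.1-fold), Mmp2 (5.26-fold) and Timp2 (4.40-fold) fell, while the inhibitor Timp1 rose 10.5-fold and Mmp9 2.75-fold. Of 16 matricellular genes 4 rose and 9 fell (4 and 9 adjusted over the list alone; median -0.76, camera adjusted p = 0.122). Fbln1 (6.39-fold) and Spon2 (3.75-fold) fell, Ccn4 rose 9.38-fold and Tnc rose at least 3.13-fold, since no young quiescent array detected it. Of 13 growth factor genes that act on muscle cells 5 fell and 0 rose (5 and 0 adjusted over the list alone; median -0.44, camera adjusted p = 0.0102, adjusted p = 0.119 with an estimated correlation), namely Fgf10 (10.3-fold), Igf2 (7.41-fold), Mdk (4.29-fold) and Fst (2.25-fold) among the named ones. Fgf10 was detected on 1 of 6 young activated arrays, so its fold rests on a level near background.

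Inflammatory genes rose in the young activated arrays together with markers of macrophages. Of 25 cytokine and chemokine genes 14 rose and 2 fell (14 and 2 adjusted over the list alone; median 0.87, camera adjusted p = 0.000321, adjusted p = 0.0652 with an estimated correlation). The chemokines Ccl12 (23.1-fold), Ccl2 (11.0-fold), Cxcl2 (9.40-fold) and Ccl7 (8.30-fold) rose, and Ccl11 (3.58-fold) and Cxcl13 (2.79-fold) fell. All 16 macrophage and monocyte genes rose (16 adjusted over the list alone; median 3.09, camera adjusted p = 1.24e-10, adjusted p = 0.0965 with an estimated correlation), with Ms4a6d up 23.6-fold, Ms4a7 17.2-fold, Ctss 12.5-fold and Fcer1g 12.3-fold. Trem2 (28.7-fold), Clec4d (20.0-fold), Arg1 (10.3-fold) and Chil3 (at least 14.3-fold), which macrophages express, rose as well. Arg1 was detected on 1 and Clec4d on 2 of 6 young quiescent arrays, near background. Interferon response genes rose in 15 and fell in 1 of 23 cases (15 and 2 adjusted over the list alone; median 0.92, camera adjusted p = 0.000176, adjusted p = 0.125 with an estimated correlation). Oasl2 (5.90-fold), Isg15 (5.36-fold), Dhx58 (5.04-fold) and Irf7 (3.96-fold) rose and Irf1 fell 2.34-fold. Of 6 lymphocyte genes 1, Prf1, fell (2.10-fold) and 0 rose (1 and 0 adjusted over the list alone; median -0.03, camera adjusted p = 0.763).

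Of 15 glycolysis genes 9 rose and 0 fell (9 and 0 adjusted over the list alone; median 0.58, camera adjusted p = 0.00191), with Pkm up 3.17-fold, Ldha 2.91-fold, Gapdh 2.88-fold and Eno1b at least 1.35-fold. Complement and coagulation genes fell in 9 and rose in 2 of 12 cases (9 and 2 adjusted over the list alone; median -1.26, camera adjusted p = 0.000418). Serping1 (6.43-fold), C2 (4.87-fold) and Cd59a (4.73-fold) fell, and F10 (9.84-fold, detected on 1 of 6 quiescent arrays) and F13a1 (2.72-fold) rose. Endothelial markers moved down with the stromal genes: 12 of 14 fell and 0 rose (12 and 0 adjusted over the list alone; median -2.64, camera adjusted p = 1.15e-09). Robo4 was 12.1-fold, Flt1 11.5-fold, Gpihbp1 11.3-fold, Emcn 10.2-fold and Pecam1 5.07-fold lower. Of 3 red blood cell genes, too few for a list test, 2 fell (3 adjusted over the list alone; median -2.69), and their score was 8.68 ± 0.34 (SD, n = 6) in quiescent and 5.91 ± 0.27 in activated young arrays. Il6 (log2 change 0.28 ± 0.37), Il33 (0.42 ± 0.24), Igf1 (-0.33 ± 0.17), Pparg (0.67 ± 0.29), Cdkn1a (-0.09 ± 0.28) and Cdkn2a (0.39 ± 0.25) did not pass the test in young arrays. Cdkn2a was detected on 0 of 6 young quiescent and 3 of 6 young activated arrays. The Cdkn2a value therefore lies near background and cannot show a lack of change.

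In all, 2559 of 7576 genes differed between young activated and quiescent arrays, 1292 higher and 1267 lower, of which 1581 changed at least 2-fold, and 22 of 34 tested gene lists passed camera (9 with an estimated correlation). Where only probes detected on all 24 arrays were tested the count was 1502 of 3577 genes. With macrophage, lymphocyte and endothelium scores as covariates, an alternative chosen after seeing the data, 0 genes passed. Of the variance of these scores 79.0%, 66.2% and 83.0% lay between groups. The unscaled standard error of the contrast, without the residual spread, grew 4.44 times.

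In old mice many of the same genes differed between activated and quiescent arrays. Arg1 rose 27.7-fold (log2 change 4.79 ± 0.34, adjusted p = 1.77e-09, 6 of 6 arrays; detected on 1 of 6 quiescent arrays), Tk1 15.5-fold, Chil3 14.8-fold, Cdca3 14.5-fold, Kif2c 14.2-fold, Clec4d 14.0-fold and Trem2 10.7-fold, where Tk1 and Kif2c were detected on 2 of 6 quiescent arrays, near background. H2ac7, H2ac11 and H2ac15 rose 8.94-, 8.56- and 8.47-fold. Ces1d (20.3-fold), Cldn10 (17.2-fold), Inmt (14.7-fold), P2ry1 (12.9-fold), Wfdc1 (12.2-fold), Ltbp4 (10.6-fold), Camk2n1 (10.1-fold), Timp3 (8.42-fold), Retnla (8.31-fold) and Pi16 (7.68-fold) fell. All 15 mitosis genes rose (15 adjusted over the list alone; median 2.21, camera adjusted p = 1.28e-15), Cenpa by 11.4-fold, Cdc20 by 6.52-fold and Plk1 by 6.24-fold, and 19 of 23 DNA replication genes rose and 0 fell (19 and 0 adjusted over the list alone; median 1.68, camera adjusted p = 3.88e-13), with Mcm5 up 10.1-fold, Mcm10 8.11-fold (detected on 1 of 6 quiescent arrays) and Rrm1 5.98-fold. Of 20 FAP and fibroblast genes 14 fell and 1, Thy1, rose 1.76-fold (15 and 1 adjusted over the list alone; median -1.06, camera adjusted p = 1.63e-08, adjusted p = 0.0666 with an estimated correlation). Vit (5.00-fold), Lum (4.43-fold) and Gsn (at least 2.58-fold) fell, and Pdgfra was 2.14-fold lower (adjusted p = 0.000547, 6 of 6 arrays). As in young arrays, the macrophage score rose beside this fall. Macrophages express Arg1, Chil3, Clec4d and Trem2, so the rise of these genes was not told apart from a change in the mix of cells.

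Of 15 basement membrane and collagen VI genes 13 fell and 0 rose in old arrays (14 and 0 adjusted over the list alone; median -1.06, camera adjusted p = 4.84e-09), including Col15a1 (4.70-fold), Lamc1 (4.01-fold), Nid2 (3.65-fold) and Nid1 (3.18-fold). In TGF-beta and BMP signalling 11 of 20 fell and 1 rose (13 and 1 adjusted over the list alone; median -0.73, camera adjusted p = 4.88e-06): Bmp4 (7.81-fold), Inhba (6.62-fold) and Ltbp1 (4.31-fold) fell and Tgif1 rose 2.18-fold. Matrix proteases and inhibitors fell in 8 and rose in 1 of 17 cases (8 and 2 adjusted over the list alone; median -0.77, camera adjusted p = 0.00507, adjusted p = 0.122 with an estimated correlation), with Mmp2 down 3.20-fold, Timp2 2.70-fold and Timp1 up 4.67-fold. Matricellular genes fell in 9 and rose in 3 of 16 cases (9 and 3 adjusted over the list alone; median -0.74, camera adjusted p = 0.0499, adjusted p = 0.261 with an estimated correlation): Fbln1 (7.15-fold), Spon2 (3.58-fold) and Thbs3 (2.75-fold) fell, and Ccn4 (3.85-fold) and Ccn5 (2.64-fold) rose. The list no longer passed without old quiescent array 1, 2, 5 or 6 or old activated array 1, 2, 4 or 5 (adjusted p = 0.0518 to 0.109). Of 13 growth factors acting on muscle cells 4 fell and 0 rose (4 and 0 adjusted over the list alone; median -0.58, camera adjusted p = 0.00413, adjusted p = 0.122 with an estimated correlation), namely Fgf10 (8.80-fold, detected on 1 of 6 activated arrays), Igf2 (7.52-fold), Mdk (6.51-fold) and Vegfa (2.48-fold). Acta2 was 2.75-fold and Il33 1.68-fold lower.

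Of 25 cytokine and chemokine genes 10 rose and 4 fell in old arrays (10 and 6 adjusted over the list alone; median 0.39, camera adjusted p = 0.0892). Ccl12 (8.38-fold), Il1b (8.07-fold), Ccl9 (7.19-fold) and Ccl3 (6.17-fold) rose, and Ccl11 (6.10-fold) and Ccl5 (2.30-fold) fell. Macrophage markers rose in 15 of 16 cases (16 adjusted over the list alone; median 2.06, camera adjusted p = 2.62e-08, adjusted p = 0.15 with an estimated correlation), including Ms4a6d (10.9-fold), Fcer1g (7.66-fold), Tyrobp (6.20-fold) and Ms4a7 (5.25-fold). Their score was 9.24 ± 1.30 (SD, n = 6) in old quiescent and 11.3 ± 0.33 in old activated arrays. Interferon response genes rose in 7 and fell in 1 of 23 cases (11 and 2 adjusted over the list alone; median 0.62, camera adjusted p = 0.0113, adjusted p = 0.307 with an estimated correlation): Ifit3 (4.96-fold), Dhx58 (4.78-fold), Usp18 (3.99-fold) and Rsad2 (3.18-fold) rose and Irf1 fell 2.59-fold. Lymphocyte genes fell in 4 of 6 cases (4 adjusted over the list alone; median -1.31, camera adjusted p = 0.00478, adjusted p = 0.15 with an estimated correlation), namely Cd3g (4.66-fold), Cd3d (3.76-fold), Cd2 (2.87-fold) and Nkg7 (2.06-fold), of which Cd3g and Cd2 were detected on 1 of 6 activated arrays, near background. Glycolysis genes rose in 7 and fell in 1 of 15 cases (8 and 1 adjusted over the list alone; median 0.45, camera adjusted p = 0.0119, adjusted p = 0.109 with an estimated correlation), with Pkm up 3.37-fold, Ldha 2.73-fold and Gapdh 2.49-fold and Pfkm down 2.86-fold. Complement and coagulation genes fell in 8 and rose in 2 of 12 cases (8 and 2 adjusted over the list alone; median -0.92, camera adjusted p = 0.0024): Serping1 (4.69-fold) and C2 (4.10-fold) fell, and F10 (9.58-fold) and F13a1 (5.24-fold) rose. Endothelial markers fell in 5 and rose in 0 of 14 cases (5 and 1 adjusted over the list alone; median -0.69, camera adjusted p = 0.00345, adjusted p = 0.21 with an estimated correlation), with Tek down 3.23-fold, Vwf 3.14-fold, Flt1 2.74-fold and Ramp2 2.63-fold. All 3 red blood cell genes fell (3 adjusted over the list alone; median -1.69), with a score of 8.92 ± 0.99 (SD, n = 6) in old quiescent and 7.17 ± 0.43 in old activated arrays.

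Between old activated and quiescent arrays 2155 of 7576 genes differed, 1097 higher and 1058 lower, of which 1294 changed at least 2-fold. Camera passed 22 gene lists (5 with an estimated correlation). How much of this came from the mix of cells was not tested. With probes detected on all 24 arrays the count was 1291 of 3577, and with the cell type scores as covariates 17 genes passed, the unscaled standard error growing 2.89 times. With cell type scores as covariates 0 genes were called in both ages. Without covariates, in both ages 811 genes rose and 765 fell, where independent lists would share 187 and 177, and 2 genes were called in opposite directions. Across genes, which are not independent replicates, the changes in the 2 ages correlated with r = 0.825. Of the 1576 genes shared, 65.4% had the smaller change in old FAPs, with a median absolute log2 change of 1.35 in young and 1.24 in old.

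In quiescent FAPs, genes of immune cells were higher in old mice, and Sparc and Thy1 were among 12 genes that were lower. Saa3, an acute phase protein, was 25.4-fold higher (log2 difference 4.67 ± 0.81, adjusted p = 0.00657, 6 of 6 old arrays). Mzb1, a gene of B cells and plasma cells, was 7.17-fold, Lat2 7.12-fold, the chemokine Ccl12 6.48-fold, the T cell receptor component Cd3d 6.32-fold, the B cell receptor component Cd79b 5.87-fold, Sla 5.83-fold, Ccl8 5.78-fold, Cd52 5.27-fold and Ccl5 5.14-fold higher. Of 25 cytokine and chemokine genes 6 were higher and 0 lower (8 and 0 adjusted over the list alone; median 0.58, camera adjusted p = 1.27e-09, adjusted p = 0.0175 with an estimated correlation), Ccl4 by 3.73-fold, and every old quiescent array scored above every young one. Of 6 lymphocyte genes 3 were higher (5 adjusted over the list alone; median 1.73, camera adjusted p = 4.87e-08, adjusted p = 0.0363 with an estimated correlation); Cd3g was at least 3.33-fold higher, since no young quiescent array detected it. Of 16 macrophage genes 3 were higher (13 adjusted over the list alone; median 1.43, camera adjusted p = 4.05e-14, adjusted p = 0.215 with an estimated correlation), namely Cd52, Aif1 (4.83-fold) and Laptm5 (1.85-fold). The macrophage score was 11.35, 9.964 and 9.56 in old quiescent arrays 2, 1 and 6 and 8.096, 8.096 and 8.378 in arrays 3, 4 and 5, against at most 8.182 in young, and the list median was 0.936 without old quiescent array 2. Mzb1, Cd3d and Sla were detected on 1 of 6 young quiescent arrays, near background. The lymphocyte score was 6.21 ± 0.18 (SD, n = 6) in young and 7.83 ± 0.91 in old quiescent arrays. In the interferon response 1 of 23 genes, Oasl2, was higher (1 adjusted over the list alone; 2.93-fold; list median 0.32, camera adjusted p = 0.00051, adjusted p = 0.256 with an estimated correlation).

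Lower in old quiescent FAPs were Abi3bp (3.67-fold), Cachd1 (3.49-fold), the matricellular protein Sparc (3.08-fold, adjusted p = 0.00819, 6 of 6 arrays), Alg1 (2.97-fold), Thy1 (2.46-fold), Itm2a (2.43-fold), Zfp979 (2.30-fold), Scg3 (2.21-fold), Rerg (2.13-fold), Id1 (2.08-fold) and Sephs1 (at least 1.37-fold). The other probe of Abi3bp had the opposite sign. Scg3 was detected on 1 and Alg1, Cachd1 and Rerg on 2 of 6 old quiescent arrays, near background. Thy1 was the 1 called gene of the FAP and fibroblast list, whose 20 members had a median of -0.17 (1 adjusted over the list alone; camera adjusted p = 0.0244, adjusted p = 0.53 with an estimated correlation; 0.33 without old quiescent array 2 and 0.0647 without array 1). Sparc was the 1 called of 16 matricellular genes (1 adjusted over the list alone; median 0.02, mean -0.14, camera adjusted p = 0.688). Id1 was the 1 called of 20 TGF-beta and BMP genes (3 adjusted over the list alone; median -0.17, camera adjusted p = 0.0418, adjusted p = 0.223 with an estimated correlation; 0.117 without old quiescent array 2, 0.0866 without array 6 and 0.0562 without array 4, and 0.0531, 0.0553 and 0.0593 without young quiescent array 1, 4 and 6). Pdgfra (log2 difference -0.10 ± 0.22), Acta2 (-0.24 ± 0.24), Pecam1 (-0.67 ± 0.35), Igf1 (0.11 ± 0.17), Pparg (-0.22 ± 0.29), Il33 (0.58 ± 0.24), Cdkn1a (0.34 ± 0.28), Cdkn2a (0.37 ± 0.25) and Il6 (1.18 ± 0.37, adjusted p = 0.132, 6 of 6 arrays) did not pass. Cdkn2a was detected on 0 of 6 young and 1 of 6 old quiescent arrays, so its value lies near background.

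In total 46 genes differed by age in quiescent FAPs, 34 higher and 12 lower, and 13 gene lists passed camera (2 with an estimated correlation; 7 by camera without old quiescent array 2). The count depended on the fit: 2 genes, both lower in old, passed when only the 12 quiescent arrays were fitted, 29 with median scaling, 30 without the filter, 78 with array weights and 1 with cell type scores as covariates. It was 28 without young quiescent array 2 and 105 without old quiescent array 4. Median scaling gave 14 higher and 15 lower (48.3% higher, against 73.9%). The median difference of all genes was then -0.146, against -0.0127 in the main fit. Without background correction the split was 29 and 26.

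**Figure D2:**
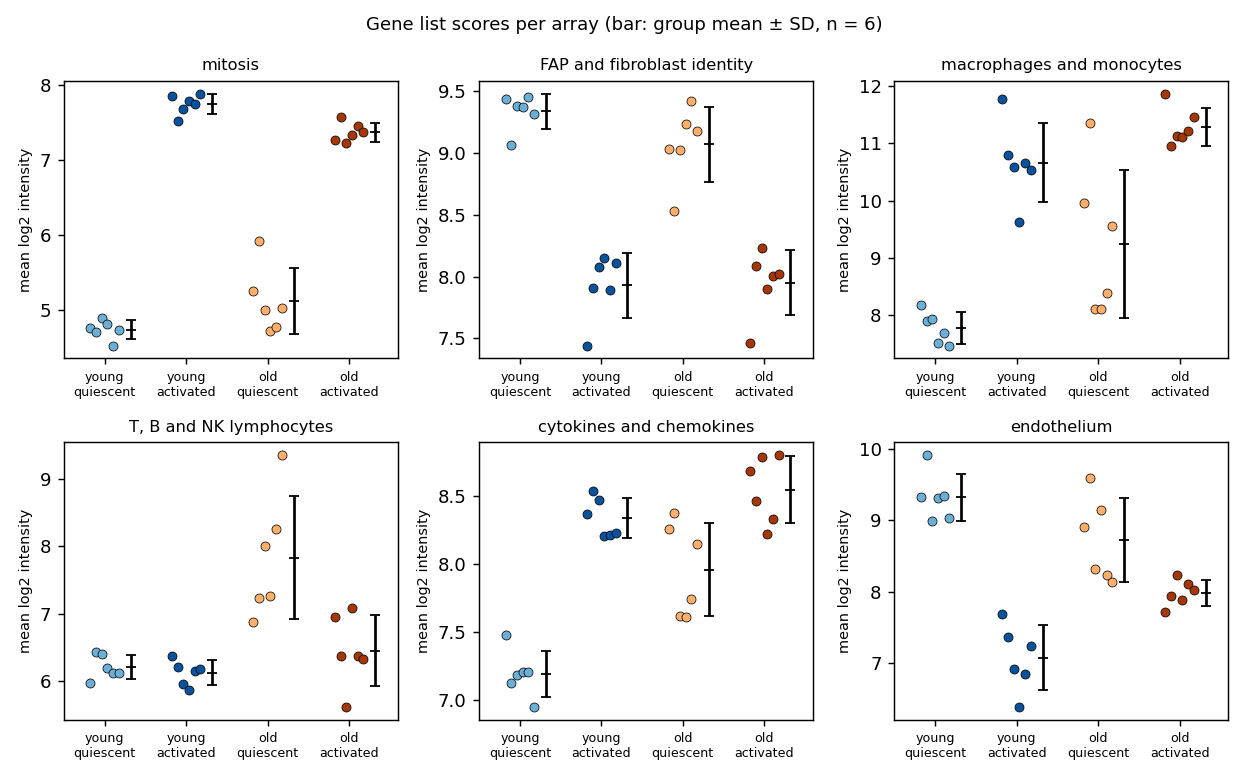
Mean log2 intensity of 6 gene lists on each of 24 arrays, by group; points are arrays and bars the group mean ± SD (n = 6). The lymphocyte score averaged 7.83 in old quiescent arrays against 6.21 in young quiescent arrays, and the endothelium score 7.98 in old activated against 7.07 in young activated arrays.

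In activated FAPs, 18 genes were higher in old mice, among them Hba-a1, 2 of 14 genes of the endothelium list and 1 of 15 genes of the muscle fibre list. Called genes outside the lists were not sorted by cell type, so these counts are not totals for a cell type. Rbp7 was 4.82-fold (log2 difference 2.27 ± 0.28, adjusted p = 0.000122, 6 of 6 old arrays) and the haemoglobin gene Hba-a1 4.76-fold higher. The endothelial genes Robo4 and Gpihbp1 were 4.47- and 4.25-fold, Tnnt3, a troponin of fast muscle fibres, 3.92-fold, Ednrb 3.76-fold, Tcf15 3.54-fold, Sult1a1 3.45-fold, Cstdc4 at least 2.31-fold and Kank3 2.70-fold higher. Of 14 endothelial genes 2 were higher and 0 lower (6 and 0 adjusted over the list alone; median 0.86, camera adjusted p = 5.85e-09, adjusted p = 0.114 with an estimated correlation), and every old activated array scored above every young one. Of 15 muscle fibre genes 1 was higher (9 adjusted over the list alone; median 1.03, camera adjusted p = 3.58e-08, adjusted p = 0.192 with an estimated correlation). Old activated array 1 scored 8.546 on this list and the others at most 7.108, and without it the median was 0.635 (camera adjusted p = 1.11e-05). Among 3 measured red blood cell genes, too few for a list test, Hba-a1 was called (1 adjusted over the list alone). Complement and coagulation genes had a median of 0.50, with 1 of 12, C4b, 2.55-fold higher (4 adjusted over the list alone; camera adjusted p = 8.44e-05, adjusted p = 0.0174 with an estimated correlation). Vit was the 1 called of 20 FAP and fibroblast genes, 2.64-fold higher (3 higher and 2 lower adjusted over the list alone; list median -0.07, mean 0.02, camera adjusted p = 0.779).

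Rbfox1 (5.58-fold), Aldh1l2 (4.11-fold) and Kdelr2 (2.09-fold) were lower in old activated FAPs, each in 6 of 6 arrays. Pecam1 (1.20 ± 0.35), Cdkn1a (0.99 ± 0.28, adjusted p = 0.116, 6 of 6 arrays), Acta2 (-0.79 ± 0.24), Il33 (-0.59 ± 0.24), Pparg (-0.24 ± 0.29), Pdgfra (-0.17 ± 0.22), Cdkn2a (-0.07 ± 0.25), Il6 (0.04 ± 0.37) and Igf1 (0.08 ± 0.17) did not pass. The Cdkn2a value again lies near background. In total 21 genes differed, 18 higher and 3 lower, and 12 gene lists passed camera (1 with an estimated correlation; 7 by camera without young activated array 4). The count was 8 with median scaling, 37 with probes detected on all 24 arrays, 43 with a variance trend, 132 with array weights and 1 with cell type scores as covariates. It was 103 without young activated array 1, 10 without array 3, 13 without array 4 and 11 without array 5 of the same group. Without background correction 18 were higher and 10 lower (64.3% higher, against 85.7%). No gene was called by age in both states: limma called 0, with 964 genes at an unadjusted p under 0.05 in quiescent and 864 in activated FAPs. Independent lists of these sizes would share 0.0808 higher and 0.00475 lower genes, so 0 says little about a difference between the states. Across genes, which are not independent replicates, the age differences in the 2 states correlated with r = 0.186. The count of genes called in both states was 2 with probes detected on all 24 arrays and 4 with array weights, and it was 2 without young activated array 1, 1 without young activated array 2 and 1 without old activated array 1.

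The activation change itself differed between ages for 15 genes, 13 with the more positive change in old and 2 with the more negative, and 8 gene lists passed camera (1 with an estimated correlation; 5 by camera without old quiescent array 2). Most positive were Tcf15 (log2 difference 3.00 ± 0.50, adjusted p = 0.009), Robo4 (2.94 ± 0.52), Sult1a1 (2.84 ± 0.53), Gpihbp1 (2.77 ± 0.48), Cachd1 (2.56 ± 0.42), Icam2 (2.31 ± 0.49), Hba-a1 (2.31 ± 0.40) and Rbp7 (2.27 ± 0.40), with n = 6 per group. Robo4 measured 10.35 ± 0.44 (SD) in young quiescent and 6.75 ± 0.76 in young activated arrays, and 9.57 ± 0.86 and 8.91 ± 0.53 in old quiescent and activated arrays. Angptl4 (-2.98 ± 0.60), a secreted regulator of lipoprotein lipase, and Stau2 (-2.11 ± 0.41) had the more negative change in old. Of 14 genes of the endothelium list 2 were called (9 adjusted over the list alone, 13 positive, median 1.66, camera adjusted p = 1.8e-13, adjusted p = 0.0476 with an estimated correlation). Called genes outside that list, such as Icam2 and Rbp7, were not sorted by cell type. Ltbp4 was the 1 called of 20 TGF-beta and BMP genes (3 adjusted over the list alone; 1.495 ± 0.283; list median 0.04, camera adjusted p = 0.236), and Hba-a1 the 1 called of 3 red blood cell genes (1 adjusted over the list alone). Pdgfra (-0.06 ± 0.31), Pecam1 (1.86 ± 0.50, adjusted p = 0.139), Il33 (-1.17 ± 0.34), Il6 (-1.14 ± 0.52), Cdkn1a (0.65 ± 0.40), Cdkn2a (-0.44 ± 0.36), Acta2 (-0.54 ± 0.33), Igf1 (-0.04 ± 0.24) and Pparg (-0.03 ± 0.40) did not pass. Here too the Cdkn2a value rests on levels near background. The count of called genes was 6 with median scaling (6 higher, 0 lower), 9 without the filter, 28 with array weights and 0 with cell type scores as covariates. It was 39 without old quiescent array 2, 28 without old quiescent array 4, 24 without young activated array 1 and 10 without young quiescent array 2.

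Ccn4, which encodes the secreted matricellular protein WISP1, was measured by 1 probe. It rose by 3.23 ± 0.49 in young FAPs (9.38-fold; adjusted p = 1.51e-05, exact permutation p = 0.00216) and by 1.95 ± 0.49 in old FAPs (3.85-fold; adjusted p = 0.00418, exact permutation p = 0.013), higher in 6 of 6 activated arrays each time. Its level was 6.21 ± 1.04 (SD, n = 6) in young quiescent, 9.44 ± 0.36 in young activated, 5.42 ± 0.94 in old quiescent and 7.36 ± 1.09 in old activated arrays. Ccn4 was detected on 5 of 6 young quiescent, 3 of 6 old quiescent and 6 of 6 activated arrays of each age. Its values that involve quiescent arrays therefore rest partly on levels near background. Old activated array 4 lay near background too, with Ccn4 at 5.713 where the lowest detected signal of that array was 5.641. Without background correction its activation change was 2.21 in young and 0.987 in old FAPs. It was 2.15 and 0.949 on the authors' values and 2.69 and 1.36 with an offset of 50. Between activated arrays Ccn4 differed by -2.08 ± 0.49 (old minus young, 4.22-fold lower), in 6 of 6 arrays, with an exact 2-sided permutation p of 0.00216 taken alone, the smallest that 924 assignments can give. Ccn4 was chosen because the study of these arrays is known for it, so this exact test is not independent of these data. Over all genes the adjusted p was 0.0652, which misses the threshold. It was 0.00481 without background correction, 0.0046 on the authors' values, 0.016 with an offset of 50, 0.0299 with array weights and 0.0471 with a variance trend. The other settings, apart from single arrays left out, did not bring it under the threshold. With 1 array left out it ranged from 0.0397 to 0.191 and was under the threshold without young activated array 1 (0.0397), old activated array 2 (0.0496) and old activated array 6 (0.0474). Ccn4 in quiescent arrays (-0.79 ± 0.49, adjusted p = 0.524, exact permutation p = 0.19, lower in 4 of 6 old arrays) and its interaction (-1.28 ± 0.69, adjusted p = 0.635) did not pass. With cell type scores as covariates the activation change of Ccn4 was 0.23 in young (adjusted p = 0.998) and -0.57 in old FAPs (adjusted p = 0.919).

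**Figure D3:**
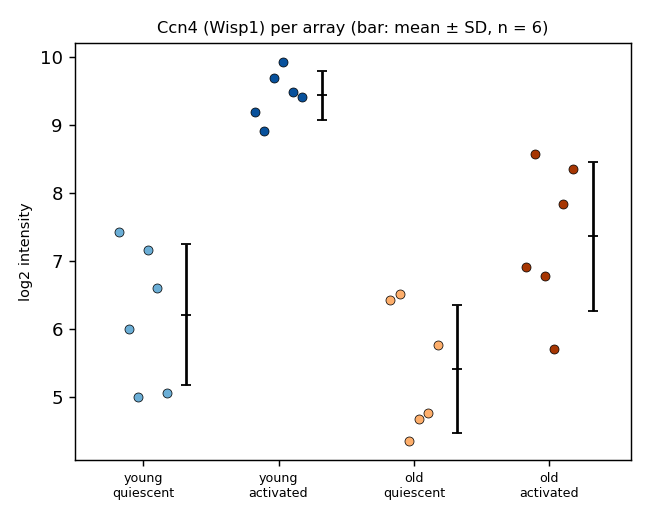
Log2 intensity of Ccn4 on each of 24 arrays by group; points are arrays and bars the mean ± SD (n = 6). The highest old activated array, at 8.58, lies below the lowest young activated array, at 8.92.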

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

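The tests of immune, endothelial and Ccn4 patterns below were chosen after the results were seen, except that the test of a weaker activation of all genes and those of other groupings of the arrays were written down before. Values of 147 genes, 35 gene lists and 2 array measures (probes detected and median signal) on the 6 arrays of each group were compared, and 83 had 1 array far from the other 5, where Dixon's rule picks about 1 in 20 groups by chance (36.8 of 736). The arrays named most often were old quiescent array 2 (14 times), old activated array 3 (10) and young activated array 1 (9). The value in parentheses is the gap of that array to its nearest neighbour, divided by the range of the group.

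Array 1 of the young quiescent group was the highest for Clec4d (0.67), F10 (0.838), Laptm5 (0.653), Ltbp1 (0.641), Mcm10 (0.833) and the tenocytes score (0.656). Array 2 was the lowest for C4b (0.752), Igf1 (0.71), Pi16 (0.667) and the FAP and fibroblast identity score (0.658). Array 2 was the highest for Icam2 (0.78), Vwf (0.649) and the contractile and myofibroblast genes score (0.717). Array 3 was the lowest for Cdkn1a (0.627). Array 3 was the highest for Arg1 (0.673), Cd3d (0.632), Cdc20 (0.664), Kif2c (0.805) and Mzb1 (0.653). Array 6 was the lowest for Inhba (0.911), Ldha (0.632), Nkg7 (0.635) and Timp2 (0.656). Array 6 was the highest for Tgif1 (0.674) and the ribosome biogenesis score (0.754).

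Array 1 of the young activated group was the lowest for Alg1 (0.625), Fbln1 (0.745), Fst (0.792), Ltbp1 (0.712), Pdgfra (0.767), Timp1 (0.717), the FAP and fibroblast identity score (0.639) and the aldehyde, retinoid and xenobiotic metabolism score (0.673). Array 1 was the highest for the Schwann cells and nerve score (0.824). Array 3 was the lowest for H2ac15 (0.662). Array 4 was the lowest for Ednrb (0.678) and Laptm5 (0.654). Array 4 was the highest for Bmp4 (0.721) and Cd3g (0.783). Array 6 was the highest for Itm2a (0.703) and Rerg (0.811).

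Array 1 of the old quiescent group was the highest for Ccl2 (0.767) and Sephs1 (0.733). Array 2 was the lowest for Col15a1 (0.713), Lamc1 (0.649), Ltbp1 (0.659), Mdk (0.712), Nid1 (0.684), Nid2 (0.648), P2ry1 (0.641), Pdgfra (0.699) and the basement membrane and collagen VI score (0.628). Array 2 was the highest for Arg1 (0.96), F13a1 (0.643), Mcm10 (0.78), Rbp7 (0.663) and the satellite cells and myoblasts score (0.75). Array 3 was the lowest for Sla (0.76) and Usp18 (0.636). Array 6 was the highest for Cdkn2a (0.69).

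Array 1 of the old activated group was the lowest for Chil3 (0.771). Array 1 was the highest for Cd3g (0.778), Rsad2 (0.658), Tyrobp (0.746) and the myofibres score (0.793). Array 2 was the highest for Mzb1 (0.666). Array 3 was the lowest for Prf1 (0.692). Array 3 was the highest for Cldn10 (0.655), Cxcl13 (0.679), Fgf10 (0.764), Gsn (0.649), Il1b (0.8), Inmt (0.632), Serping1 (0.716), Sult1a1 (0.718) and the adipogenesis score (0.772). Array 4 was the lowest for Cd59a (0.765), Flt1 (0.677), Il33 (0.828), Irf1 (0.849) and Thbs3 (0.668). Array 4 was the highest for F10 (0.74). Array 6 was the highest for Eno1b (0.666).

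The activation change differed between ages for 15 genes by a test of the difference itself (old minus young, log2): Tcf15 (3.00), Robo4 (2.94), Sult1a1 (2.84), Gpihbp1 (2.77), Cachd1 (2.56), Icam2 (2.31), Hba-a1 (2.31), Rbp7 (2.27), Slc9a3r2 (2.07), Cavin2 (1.96), Lims2 (1.68), Mgll (1.59), Ltbp4 (1.5), Stau2 (-2.11) and Angptl4 (-2.98). It differed for 8 gene lists by camera, with medians of -0.578 for mitosis, -0.399 for DNA replication, -0.642 for cytokines and chemokines, -0.213 for the interferon response, -0.759 for macrophages (-0.304 without old quiescent array 2), -1.59 for lymphocytes, 1.66 for endothelium and 0.956 for myofibres, where 2 endothelial genes and 0 genes of the other 7 lists were called. With an estimated correlation only endothelium passed (adjusted p = 0.0476), and mitosis (0.0796), DNA replication (0.402), cytokines (0.0923), interferon response (0.487), macrophages (0.487), lymphocytes (0.198) and myofibres (0.47) did not.

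Other groupings of the same arrays were drawn 100 times, the real one included, and the number with as large a result is given with the real value and the highest other. For activation in young FAPs it was 1 for genes (2559 against 681) and 7 for gene lists (22 against 24). For activation in old FAPs it was 1 for genes (2155 against 1335) and 1 for lists (22 against 19). For age in quiescent FAPs it was 1 for genes (46 against 9) and 6 for lists (13 against 14). For age in activated FAPs it was 2 for genes (21 against 39) and 4 for lists (12 against 14). For the interaction it was 1 for genes (15 against 3) and 26 for lists (8 against 14), and for genes shared by both ages 1 (1576 against 0). Numbers of gene lists for activation in young, age in quiescent FAPs and the interaction are therefore not set apart from other groupings. Many of these groupings mix the groups unevenly and keep part of the real difference, so they are not a pure chance level. For activation in young the median of the other groupings was 13 lists. The comparison bears on the number of lists and does not judge any single list.

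By the main fit, immune genes were higher in old quiescent FAPs. All 34 of 34 genes called higher had at least 2/3 of their difference with median scaling (median 1.89 with an SE of 0.38 before, 1.72 with an SE of 0.399 after). Their differences thus kept most of their size without quantile normalization. The test was lenient, since the genes were picked in the quantile-normalized fit. The median difference of all genes moved only from -0.0127 to -0.146. The part of normalization in the calls is not judged by this test. Only 14 of these 34 were still called, with adjusted p up to 0.282, since the differences shrank and their errors grew. The main fit pools the spread of all groups. The lymphocyte score had an SD of 0.907 in old and 0.177 in young quiescent arrays, and the macrophage score 1.3 and 0.276. With only the quiescent arrays fitted, 2 genes passed, 0 of them higher in old, while 15 gene lists passed camera. The 34 calls therefore rest on fitting all groups together. RNA of macrophages and lymphocytes among the sorted cells could cause the pattern and cannot be told apart from transcription of these genes by old FAPs, since either would raise the markers (22 of 22 were higher). An effect of age itself was not tested.

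The endothelial gene list was higher in old activated FAPs by camera, with 2 of 14 genes called, and did not pass with an estimated correlation (adjusted p = 0.114). A lower share of FAPs that raises all other cell types alike is not decided. The endothelium score was higher by 0.472 ± 0.178 (SE, n = 6) over the mean of 9 other cell types (exact 2-sided permutation p = 0.0238). It was higher by 0.904 ± 0.179 over tenocytes, Schwann cells and satellite cells, the types compared first. Red blood cells (1.26 ± 0.206), myofibres (0.903 ± 0.322), macrophages (0.626 ± 0.311) and neutrophils (0.526 ± 0.135) had higher means too. So had lymphocytes (0.328 ± 0.228), pericytes (0.284 ± 0.0878), Schwann cells (0.209 ± 0.165) and tenocytes (0.0591 ± 0.0817), and only satellite cells a lower one (-0.244 ± 0.167). In young activated arrays satellite cells (5.60) and red blood cells (5.91) lay nearer to background than endothelium (7.07), while macrophages (10.66) lay higher. Background and the offset shrink log2 differences of dim genes, so equal rises cannot be judged from these scores. A single array is argued against, since the median difference of 0.86 ranged from 0.722 to 1.19 with 1 activated array left out. RNA of endothelial cells could cause the pattern and cannot be told apart from transcription by FAPs, since either would raise the markers (14 of 14 were higher), and an effect of age was not tested.

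Ccn4 was lower in old activated FAPs, by an exact test taken alone. That test is not independent of these data, since the gene was chosen because the study of these arrays is known for it. A lower share of FAPs could lower it and is not decided. The FAP identity genes had a median difference of -0.0687 and their score differed by 0.02 ± 0.152 (SE, n = 6). These genes fell with activation themselves (median -1.10 in young and -1.06 in old), so they cannot measure the share in activated arrays. Scores of the other cell types, apart from satellite cells, had higher means in old activated arrays. A single array is argued against as the source of the difference, which stayed at -1.747 or lower with 1 activated array left out. The value of -1.747 was that without old activated array 4, where Ccn4 lay near background. The adjusted p ranged from 0.0397 to 0.191. A weaker activation of all genes in the arrays is argued against, since 0% of 171 genes with a comparable rise in young FAPs were as low in old activated arrays, with a median difference of 0.09. These genes include macrophage genes such as Ctss and Ms4a7, whose list was higher in old activated arrays (median 0.70). A weaker activation of FAPs alone is therefore not tested by this set. An effect of age on Ccn4 itself stays open.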

How the results depend on the processing

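Apart from the values below, counts stayed within 1.5 times and Ccn4 kept its direction and its side of the threshold. Similar counts can hold different genes. On the authors' values age in quiescent gave 55 genes, of which 33 were among the 46 of the main fit. Age in activated gave 27, of which 15 were among the 21 of the main fit. Signals near background limit folds of dim genes, and no chip is given, so a chip block was not run. Where a cause is not stated, the cause was not tested.

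With the replicate block, in which the number in the titles is a block, the counts were 2621, 2264, 50, 28 and 15 genes for activation in young, activation in old, age in quiescent, age in activated FAPs and the interaction, and no call of Ccn4 changed. Pairs of the same number correlated over 0.1 in 0 of 6 to 3 of 6 cases per pair of groups, so not every pair did. Between young and old activated arrays it was 3 of 6 pairs (up to 0.365, mean of other numbers -0.0274), and 4 of 6 arrays correlated best with their own number, a hint from the data and not the design.

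With median scaling age in quiescent gave 29 genes, age in activated 8 and the interaction 6; without the filter age in quiescent gave 30 and the interaction 9. With probes detected on all 24 arrays, where fewer genes are tested, activation in young gave 1502, activation in old 1291 (12 lists), both ages 966, age in activated 37 and both states 2. With only the groups compared, age in quiescent gave 2. Array weights gave 78, 132 and 28 for age in quiescent, age in activated and the interaction, and 4 in both states; a variance trend gave 43 for age in activated. Ccn4 between activated arrays passed with no background correction (-1.565), the authors' values (-1.529), an offset of 50 (-1.826), array weights (-1.833) and a variance trend (-2.077). Lists past camera with an estimated correlation were 9, 5, 2, 1 and 1, and by fry 5 for age in quiescent, 7 for age in activated and 3 for the interaction.

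Chosen after seeing the data, the fit without the pair of arrays with the lowest weights (old activated 4 and old quiescent 3) gave 2770, 1927, 59, 22 and 14 genes. Also chosen after seeing the data, the fit with macrophage, lymphocyte and endothelium scores as covariates gave 0, 17, 1, 1 and 0 genes, 0 in both ages, and 12, 12, 4 and 0 lists for activation in young, activation in old, age in quiescent and the interaction. These scores overlap with the groups: unscaled standard errors, without the residual spread, grew 4.44, 2.89, 1.85, 1.54 and 1.75 times. Each score is the mean of its own list's members, so the fit sets the mean change of those members to 0. Turned signs of the macrophage, lymphocyte and endothelium lists, and of members such as Pecam1, Ctss and Cd79b, follow from the fit and are no result. Of 253 named gene values 188 kept their direction but no longer passed, 20 that passed in either fit turned direction and 17 that passed in neither changed sign, and of 170 list values 31, 18 and 46. Ccn4 was 0.23 for activation in young and -0.5656 in old FAPs. Turned in activation in young were cytokines (-0.211), MHC class II (-1.40), endothelium (0.266), Ctss (-1.955), Cxcl2 (-0.3619), Dpp4 (0.7797), Emcn (1.486), Ms4a6d (-0.2551), Ms4a7 (-0.9954), Pecam1 (0.6007), Prf1 (0.7001), Robo4 (0.6002) and Trem2 (-0.7053). Turned in activation in old were lymphocytes (-0.123, by the test's direction), endothelium (0.169), Ccn5 (-0.2598), Ifit3 (-0.1252), Ms4a7 (-1.553), Nkg7 (1.243), Thy1 (-0.05012), Trem2 (-0.9017) and Usp18 (-0.3519). Turned in age in quiescent were FAP identity (0.152), DNA replication (-0.131), basement membrane (0.183), TGF-beta and BMP (0.226), macrophages (-0.131), MHC class II (-0.588), endothelium (0.0868), Aif1 (-0.1348), Ccl8 (-0.5239) and Cd79b (-1.162). Turned in age in activated were fibrillar collagens (0.0276), cholesterol synthesis (0.0492), MHC class II (-0.0426) and endothelium (-0.126), and in the interaction macrophages (0.0473) and endothelium (-0.16).

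With 1 array left out, 165 of 3258 named gene values and 63 of 2448 list values no longer passed, 0 that passed in either fit turned direction and 27 and 69 that passed in neither changed sign, and counts ranged from 2331 to 2429 for activation in young, 1954 to 2296 in old, 28 to 105 for age in quiescent, 10 to 103 for age in activated and 10 to 39 for the interaction, from 1448 to 1626 in both ages and 0 to 2 in both states. Lists ranged from 22 to 22, 17 to 22, 7 to 16, 7 to 14 and 5 to 11. Ccn4 ranged from 2.988 to 3.473, 1.70 to 2.29, -1.033 to -0.5467, -2.318 to -1.747 and -1.53 to -0.9463.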

Other observations

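The tests of a shift of old quiescent FAPs along the activation change were chosen after the result was seen, except that the test with macrophage genes removed was written down before. The following lists of metabolism and of other cell types passed camera for activation, with called genes, medians and camera adjusted p in young and then in old FAPs. The counts adjusted over the list alone are the same unless given. In oxidative phosphorylation 7 and 4 of 25 genes rose and 0 fell (0.249, adjusted p = 0.00597; 0.133, adjusted p = 0.0499; adjusted p = 0.0679 and 0.169 with an estimated correlation). In cholesterol synthesis 6 and 4 of 15 rose and 0 fell (0.638, adjusted p = 0.00191; 0.538, adjusted p = 0.0129; adjusted p = 0.1 and 0.181 with an estimated correlation). In ribosome biogenesis 6 and 5 of 15 rose and 0 fell (in young 1 fell adjusted over the list alone; 0.50, adjusted p = 0.0166; 0.616, adjusted p = 0.0499; adjusted p = 0.060 and 0.122 with an estimated correlation). Of 17 immediate early genes 10 and 8 fell and 0 rose (10 and 9 fell adjusted over the list alone; -0.838, adjusted p = 1.7e-05; -0.692, adjusted p = 0.00028; adjusted p = 0.125 and 0.200 with an estimated correlation). Of 20 genes of aldehyde, retinoid and xenobiotic metabolism 13 and 12 fell and 3 and 1 rose (14 and 13 fell adjusted over the list alone; -1.48, adjusted p = 4.38e-05; -1.38, adjusted p = 1.38e-05; adjusted p = 0.115 and 0.122 with an estimated correlation). Markers that fell, with 0 risen, were 5 and 2 of 9 for pericytes (5 and 4 adjusted over the list alone; -1.06, adjusted p = 0.00257; -0.734, adjusted p = 0.0285; adjusted p = 0.0679 and 0.169 with an estimated correlation), 5 and 4 of 6 for tenocytes (-0.914, adjusted p = 0.00226; -0.794, adjusted p = 0.00507; adjusted p = 0.0355 and 0.0635 with an estimated correlation) and 4 and 4 of 5 for Schwann cells (-1.41, adjusted p = 0.00342; -1.07, adjusted p = 0.0183; adjusted p = 0.052 and 0.122 with an estimated correlation). Of 15 muscle fibre genes 8 fell and 1 rose in young (-1.15, adjusted p = 0.00226; adjusted p = 0.279 with an estimated correlation), and in old 3 fell (1 adjusted over the list alone) with a median of -0.357 (adjusted p = 0.458). In old FAPs cholesterol synthesis (adjusted p = 0.0582) and pericyte markers (adjusted p = 0.0692) did not pass without old quiescent array 2. Ribosome biogenesis did not without old quiescent array 1, 2 or 6 or old activated array 2, 4 or 6 (adjusted p = 0.0634 to 0.0943), nor oxidative phosphorylation without old quiescent array 1, 2, 3, 4 or 6 or old activated array 1, 2, 5 or 6 (adjusted p = 0.051 to 0.104).

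Lists that did not pass camera for activation, with medians in young and old, were adipogenesis (-0.576 and -0.417), Wnt signalling (-0.354 and -0.408), fibrillar collagens (-0.196 and -0.0845), contractile genes (-0.0171 and -0.181), CDK inhibitors and p53 targets (-0.0406 and -0.0577), ER protein folding (0.568 and 0.0682), MHC class I (0.0916 and 0.176), MHC class II (0.646 and 0.366), neutrophils (0.705 and 0.487) and satellite cells (-0.027 and -0.43). Of 17 adipogenesis genes 7 fell and 1 rose in young and 5 fell and 0 rose in old. By fry adipogenesis passed (adjusted p = 8.04e-06 in young and 9.97e-05 in old). Wnt signalling (fry adjusted p = 0.000565 and 0.000636) and CDK inhibitors and p53 targets (0.00686 and 0.0203) passed too, as did contractile genes in old (0.00939). By age in quiescent FAPs camera passed further lists in which 0 genes were called, with positive medians for MHC class II (1.13, camera adjusted p = 7.32e-05), neutrophil (0.507, adjusted p = 0.0056), mitosis (0.216, adjusted p = 0.0056), DNA replication (0.261, adjusted p = 0.00188) and immediate early genes (0.314, adjusted p = 0.0113), and negative medians for endothelial (-0.675, adjusted p = 0.0004) and basement membrane genes (-0.387, adjusted p = 0.00337). Adjusted over the list alone 3 of 7, 2 of 8, 2 of 15, 0 of 23 and 1 of 17 were higher and 0 of 14 and 0 of 15 lower. With an estimated correlation these had adjusted p = 0.223, 0.223, 0.223, 0.223, 0.530, 0.223 and 0.279. Without old quiescent array 2 mitosis (0.146, adjusted p = 0.197), DNA replication (0.109, adjusted p = 0.0745), basement membrane (-0.218, adjusted p = 0.127) and neutrophil genes (0.27, adjusted p = 0.146) did not pass; nor did neutrophil (adjusted p = 0.0647) and immediate early genes (adjusted p = 0.06) without array 1, or immediate early genes (0.179, adjusted p = 0.155) without young quiescent array 6. In activated FAPs camera also passed lists in which 0 genes were called. Medians were positive for immediate early genes (0.413, adjusted p = 2.1e-07), macrophage genes (0.70, adjusted p = 0.000683), MHC class II (0.763, adjusted p = 0.0108), CDK inhibitors and p53 targets (0.448, adjusted p = 0.0209) and neutrophil genes (0.494, adjusted p = 0.0338), where 6 of 17, 0 of 16, 0 of 7, 1 of 16 and 2 of 8 were higher adjusted over the list alone. They were negative for mitosis (-0.446, adjusted p = 0.00197), contractile genes (-0.297, adjusted p = 0.0116), fibrillar collagens (-0.376, adjusted p = 0.0146) and cholesterol synthesis (-0.243, adjusted p = 0.041), where 1 of 15, 2 of 16, 0 of 19 and 0 of 15 were lower adjusted over the list alone. With an estimated correlation these 9 had adjusted p = 0.196, 0.418, 0.404, 0.192, 0.352, 0.196, 0.308, 0.404 and 0.352. Without young activated array 4 CDK inhibitors, fibrillar collagens, MHC class II and neutrophil genes (adjusted p = 0.0529 each) and cholesterol synthesis (adjusted p = 0.104) did not pass. Without old activated array 1 fibrillar collagens (adjusted p = 0.159), cholesterol synthesis (adjusted p = 0.184) and MHC class II (adjusted p = 0.0762) did not. Cholesterol synthesis was also lost without young activated array 3 or 6 or old activated array 3 or 6 (adjusted p = 0.0508 to 0.197), and neutrophil genes without young activated array 1 or 3 or old activated array 3 or 4 (adjusted p = 0.0586 to 0.0701). In the interaction mitosis (p = 3.57e-06), DNA replication (0.00175), cytokines (4.16e-05), interferon response (0.0139), macrophages (0.000616), lymphocytes (0.000284) and myofibres (0.000163) passed camera with 0 genes called (3 of 15, 0 of 23, 6 of 25, 1 of 23, 1 of 16 and 4 of 6 lower and 2 of 15 higher adjusted over the list alone), with adjusted p = 0.0796, 0.402, 0.0923, 0.487, 0.487, 0.198 and 0.470 with an estimated correlation. Without old quiescent array 2 DNA replication (adjusted p = 0.0505), interferon response (adjusted p = 0.153) and macrophages (median -0.304, adjusted p = 0.106) did not pass, and the interferon response did not without young quiescent array 6, old quiescent array 1 or old activated array 2 or 3 (adjusted p = 0.055 to 0.0885).

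Old quiescent FAPs may lie part of the way to the activated state. With separate young quiescent arrays on each side, the age difference in quiescent FAPs correlated across 7576 genes with the young activation change at r = 0.292 and 0.323, against 0.441 with shared arrays. Of 84 other groupings, the real one included, 4 and 2 were as high (highest other 0.336 and 0.331), and without old quiescent array 2 the correlations were 0.204 and 0.24, with 4 and 2 of 56 as high (highest other 0.245 and 0.244). RNA of macrophages could cause part of this: over 7030 genes that do not follow the macrophage score it was 0.192 and 0.222. The values do not decide either explanation.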
